A study of Mus musculus with 11 samples.

How the data were processed

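RNA was sequenced from mouse spinal cord and from mouse fetal fibroblasts (MEF), a primary culture made from fetuses. The C57BL/6 mice were wild-type or heterozygous for Morc2a p.S87L, a serine to leucine change in the ATPase domain of MORC2A. The labels give 3 wild-type spinal cord, 3 S87L spinal cord, 3 wild-type MEF and 2 S87L MEF libraries, and the library titles gave each library its group and replicate number. Per the labels' protocols, total RNA was taken with TRIzol and libraries were made with a strand-specific NEBNext Ultra II Directional kit. A poly(A) selection or ribosomal RNA removal step is not given in the sources used here.

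The authors deposited a table of FPKM values, fragments per kilobase of gene scaled to a read total, for 55487 Ensembl gene identifiers in 11 libraries. Per the submitters' processing notes, the tools were Trimmomatic 0.39, HISAT2 2.2.1, Picard 2.25.5 and HTSeq 0.11.3 with the mouse build GRCm38. What each tool did, the annotation release, and whether counting used the strand are not given in the sources used here. An antisense gene and its partner may therefore share reads, and so may overlapping genes and near-identical copies such as Hspa1a and Hspa1b, protocadherins, histones and clustered zinc finger genes. Symbols, gene types and coordinates came from the GENCODE annotation of GRCm38 at hand, in which 55227 identifiers were found and 260 were not. All coordinates are GRCm38.

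The deposited FPKM values move in steps of 1 read. Dividing each value by its step gave whole reads, within 0.05 of a whole number, for 98.51% to 98.6% of values per library. The divisor behind the steps was 11.48 to 22.72 M reads, close to the recovered reads of protein-coding genes (11.45 to 22.65 M). In the recovered reads, all pairs of libraries of the same group differed beyond counting noise, with chi-square per degree of freedom of 1.29 to 5.48. Each library was counted as 1 replicate. Separate preparations of the same RNA may also differ beyond counting, so this does not show separate animals or cultures. The coefficient of variation beyond counting, over genes of 1000 to 10000 reads, was 4.2% in wild-type and 3.43% in S87L spinal cord, 1.95% in wild-type and 5.76% in S87L MEF.

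Each tissue was fitted alone with limma 3.58.1 in R 4.3.3 (trend and robust settings) on log2(FPKM + 0.5), over genes with a mean FPKM of at least 0.5 in that tissue's libraries. Fold changes are on the log2(FPKM + 0.5) scale, S87L minus wild-type, and understate the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that comparison. Whether the genotype effect differed between tissues was tested as the interaction term of a limma fit of all 11 libraries. Overlap of calls was tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 4 combinations of direction. Every p-value of a gene named with limma or of a list tested with camera is from these fits, and SE is the moderated standard error.

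A set of 35 gene lists was fixed before the data were examined. Regulatory lists were the HUSH complex and partners, zinc finger genes with Zfp symbols, clustered protocadherins, Hox genes, imprinted genes and replication-dependent histones. Stress and metabolism lists were NRF2 antioxidant genes, the p53 and DNA damage response, the nuclear-encoded respiratory chain, mitochondrially encoded genes, the integrated stress response and unfolded protein response (UPR), heat shock proteins, cholesterol synthesis, immediate early genes, ribosomal proteins and proliferation. Immune and injury lists were interferon-stimulated genes, inflammatory cytokines and chemokines, and neuronal injury and regeneration. Cell type lists were microglia and macrophages, reactive astrocytes, astrocytes, motor neurons, neurons and synapses, oligodendrocytes and myelin, Schwann cells, endothelium and pericytes, meninges and fibroblasts, skeletal muscle, red blood cells, neutrophils and lymphocytes, ependyma and cilia, epithelial cells, fibroblast matrix and contractile genes, and sex-linked genes. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over lists per comparison. Camera with an estimated correlation was run beside it. Calls within a list were also counted adjusted over the list alone.

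The rule for naming genes was fixed at the same time. Per tissue it took Morc2a, then the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, with a mean FPKM of at least 1 in the higher group and no clone or predicted name. It added up to 4 members of each list with the smallest p, the 5 interaction genes with the smallest p in each direction, and 10 genes called in both tissues. Genes named outside the rule are said to have been chosen after their values were seen.

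Alternatives chosen beforehand were other pseudocounts and filters, quantile and median ratio scaling, a joint fit, the replicate number as a block, limma without trend and robust settings, library weights, leaving out each library, an estimated correlation and fry for lists, and another threshold for the overlap. Chosen after seeing the data were limma voom on the recovered reads, leaving out features with under 200 bases of exon, and removing each library's trend with GC content and length. No deposited column of the 11 libraries was left out.

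The fits were checked on simulated data. In the simulated spinal cord comparison (15702 genes, 50 changed at each size), 30%, 84%, 96% and 96% of genes changed 1.25, 1.5, 2 and 4 times were recovered, and 10 of 15502 unchanged genes were called. In the simulated MEF comparison (13597 genes, 50 at each size) the shares were 18%, 76%, 96% and 96%, and 26 of 13397 unchanged genes were called. In the simulated interaction (12213 genes, 81 to 88 at each size) they were 25.3%, 82.7%, 92.1% and 94.1%, and 20 of 11876 unchanged genes were called. Camera recovered 15 of 15 lists shifted 1.25 times and called 0 of 35 unshifted lists in each tissue, with 0 of 35 also under an estimated correlation. Each simulated group had 1 coefficient of variation beyond counting for all its genes, and changed genes were drawn from those with a mean FPKM of at least 1. The recovered shares therefore do not cover lower genes or genes with a wider spread. The calls of unchanged genes do not cover groups in which 1 library stands apart from the others. Simulated genes were drawn independently of each other. The list check therefore does not show how often camera calls unshifted lists whose genes are correlated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and figures.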

Results

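Expression was measured by RNA sequencing in spinal cord and in fetal fibroblasts (MEF) of wild-type mice and of Morc2a p.S87L heterozygotes, with 3 libraries per group and 2 for S87L MEF. MORC2A is a chromatin-associated ATPase that works with the HUSH silencing complex, and the study concerns variants of it that cause neuropathy. Depth, as the reads recovered from the FPKM values, was 18.97, 15.53 and 15.35 M reads in the wild-type and 20.43, 23.53 and 19.4 M in the S87L spinal cord libraries. It was 14.31, 14.29 and 15.05 M in wild-type MEF and 14.47 and 12.08 M in S87L MEF. The 10 genes with the most recovered reads took 5.53% to 8.59% of the recovered reads of a library. The labels do not say clearly whether the libraries of a group came from separate animals, fetuses or cultures, so the p-values measure only the spread between these libraries, which may be technical.

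Morc2a itself (chromosome 11, 3649191 to 3690477) was transcribed in all libraries. Its FPKM was 5.62, 5.66 and 5.71 in wild-type and 4.71, 4.93 and 4.95 in S87L spinal cord. In MEF it was 18.5, 18.8 and 18.3 in wild-type and 16.4 and 16.4 in S87L. The log2 fold change was -0.20 in spinal cord (SE 0.04, limma adjusted p = 0.0269) and -0.17 in MEF (SE 0.04, adjusted p = 0.0421). Both calls were near the threshold. The spinal cord call held without wild-type replicate 1 (adjusted p = 0.0478) and was lost without any other library, up to 0.0940 without S87L replicate 1. The MEF call was lost without any of the 5 libraries (adjusted p = 0.0620 to 0.161). A total over the gene does not separate the alleles, so the genotype itself was not checked by these values.

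**Figure D1:**
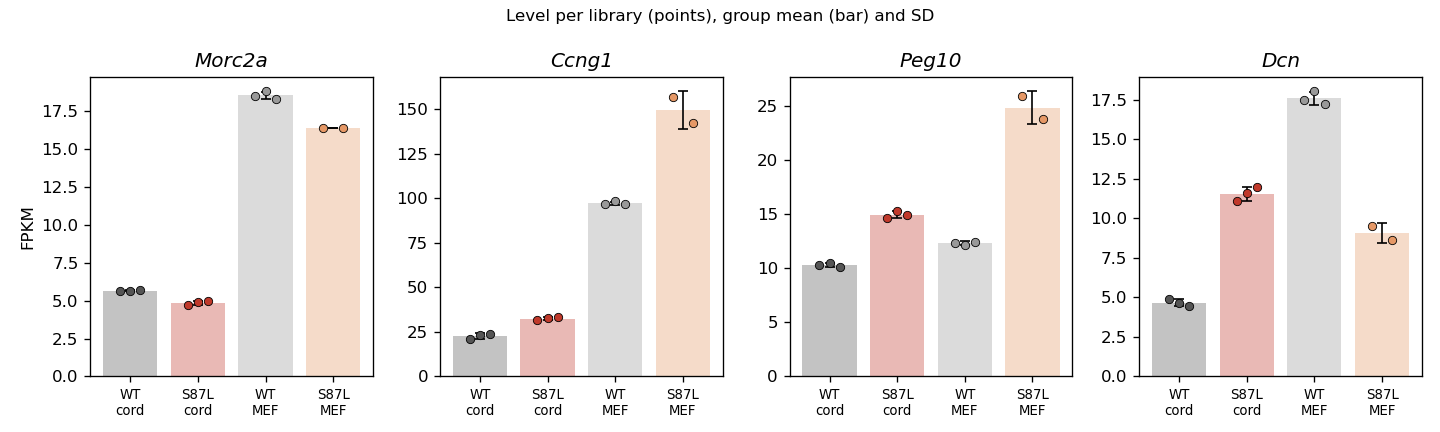
FPKM of Morc2a, Ccng1, Peg10 and Dcn in each library, by genotype and tissue. Points are libraries, bars are group means starting at 0 and error bars are SD (n = 3, and n = 2 for S87L MEF).

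The spinal cord comparison asks which transcripts differ in the tissue that holds motor neurons. Skeletal muscle transcripts rose, and transcripts of the caudal Hox genes, the apelin receptor Aplnr and several long noncoding RNAs fell. Of 15648 genes tested, limma called 2016, 809 higher and 1207 lower in S87L, against 839 and 892 with quantile normalization and 970 and 1032 with median ratio scaling. The median size of a called change was 0.32 on the log2 scale. Changes of at least 1.5-fold numbered 134 higher and 235 lower, and of at least 2-fold 34 and 92. The groups did not overlap at any of the 2016 called genes, or at 5500 of all genes tested, where chance gives 10%. Leaving out 1 library gave 1163 calls without wild-type replicate 2, 1044 without wild-type replicate 3, 908 without S87L replicate 1, 838 without S87L replicate 2 and 1213 without S87L replicate 3. The count was 3098 with library weights and 3315 with the GC and length trend removed.

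Acta1, skeletal muscle actin (chromosome 8, 123891769 to 123894751), showed the largest rise, from 3.96 ± 0.774 to 20.6 ± 1.19 FPKM (SD, n = 3 each; 4.76-fold, SE 0.11 on the log2 scale, adjusted p = 8.71e-05). On the log2 scale the oxygen carrier Mb rose by 2.21, the sarcomere proteins Tcap and Tnnc2 by 2.16 and 1.94, and the calcium pump Atp2a1 by 1.78. Creatine kinase Ckm and the fast myosins Myh2 and Myh4 rose by 1.68, 1.68 and 1.67, and the troponin Tnnt3 by 1.67. Cytl1, a secreted protein of cartilage, rose by 1.81. Of 15 tested skeletal muscle genes, 14 rose, and 14 adjusted over the list alone (median 1.67, camera adjusted p = 7.55e-20). This was the sole spinal cord list still called with an estimated correlation (adjusted p = 0.0466). Levels in wild-type cord were above 0 but low, such as 0.923 ± 0.137 FPKM for Mb.

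The receptor Aplnr, which endothelial cells use to respond to apelin, fell from 8.05 ± 0.124 to 0.725 ± 0.115 FPKM (SD, n = 3 each; chromosome 2, 85136225 to 85139923; log2 fold change -2.81, SE 0.08, adjusted p = 1.08e-05). The 9 other largest falls were microRNA features. Of 175 microRNA features tested, 49 were lower, and small RNA features within introns were lower than their host genes by a median of 0.42 on the log2 scale. Of the 9, Mir300, Mir376c, Mir539, Mir380, Mir758, Mir376a, Mir3070a and Mir323 lie between 109587943 and 109728202 on chromosome 12, beyond Meg3 on the side away from Dlk1, and Mir1942 on chromosome 15. They rest on 7 to 24 reads over the wild-type libraries and 0 to 3 over the S87L libraries, so their folds are not given. Mir380, Mir323 and Mir1942 were listed at 0 in all S87L libraries, against 7, 10 and 7 reads. With 1 library left out, the calls of 5 features were lost: Mir539 (up to 0.157, without any library but wild-type replicate 1), Mir3070a (up to 0.0848, any but wild-type replicate 2), Mir300 (up to 0.0834, wild-type replicate 1 or 2 or S87L replicate 1 or 3), Mir376a (up to 0.0855, wild-type replicate 1 or S87L replicate 1 or 2) and Mir758 (0.0536, S87L replicate 2).

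Caudal Hox genes, which set position along the body axis, were far lower in S87L cord. Hoxa10 fell from 4.62 ± 0.341 to 0.601 ± 0.0952 FPKM (log2 fold change -2.22, SE 0.09, adjusted p = 3.83e-05) and Hoxc10 from 9.20 ± 0.438 to 2.33 ± 0.190 (-1.78, SE 0.07). Hoxd9 fell by 1.42 and Hoxa9 by 1.19. All 6 tested genes of paralog groups 9 and 10 fell (median -1.31), and of the 20 in groups 1 to 8, 4 rose and 1 fell (median 0.05), a division chosen after the values were seen. Of these 5, Hoxa4 lost its call without wild-type replicate 2, S87L replicate 1 or S87L replicate 2 (adjusted p up to 0.0833), Hoxb5 without S87L replicate 1 or 2 (up to 0.0629) and Hoxd1, the lower one, with any 1 of the 6 libraries left out (up to 0.108). Over the list of 26, 4 rose and 7 fell, with the same counts adjusted over the list alone. Its median of 0.02, which was -0.01 with the GC and length trend removed, and its mean of -0.24 differed in sign, and camera did not call it lower (adjusted p = 0.507). Muscle genes rose in the same libraries (median 1.67).

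**Figure D2:**
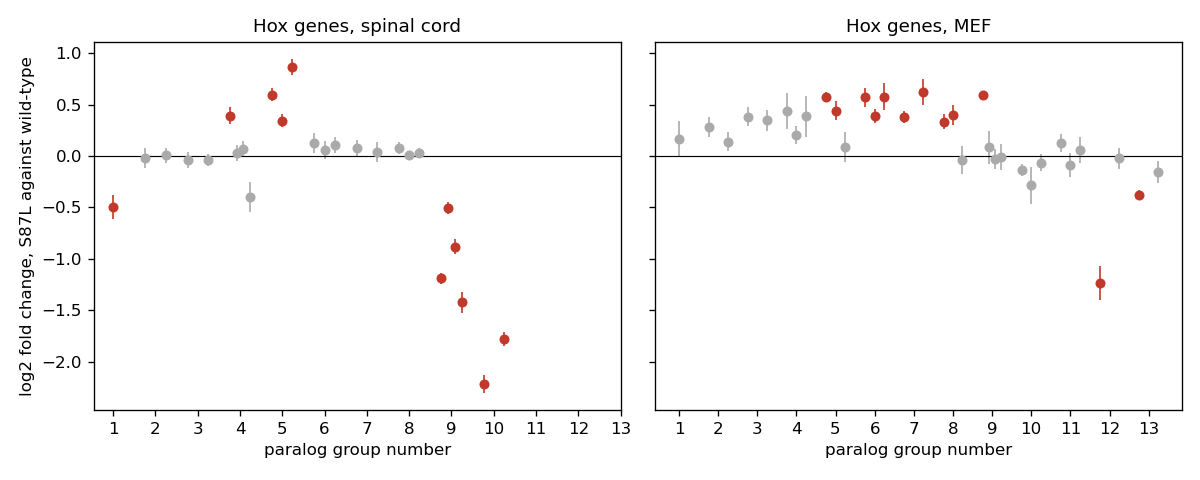
Log2 fold change (S87L minus wild-type) of each tested Hox gene against its paralog group number, in spinal cord and in MEF. Red points have a limma adjusted p under 0.05, grey points do not, and bars are SE.

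Imprinted genes moved both ways. Meg3, a long noncoding RNA (chromosome 12), fell from 92.0 ± 2.13 to 38.4 ± 0.281 FPKM (log2 fold change -1.25, SE 0.03, adjusted p = 1.08e-05), and Mirg, of the same region, fell by 0.84. In the same libraries the noncoding RNAs Malat1, Neat1, Miat and Snhg11, chosen after their values were seen, fell by 0.75, 0.85, 1.07 and 1.11, and intronic small RNA features were lower than their host genes by a median of 0.42. The growth regulator H19 and the retrotransposon-derived Peg10 rose by 0.83 and 0.52. Of 27 imprinted genes, 2 rose and 8 fell, and 2 and 10 adjusted over the list alone (camera adjusted p = 0.0851). The list was called lower without S87L replicate 3 (adjusted p = 0.0292), with quantile normalization (0.0481) and with fry (5.04e-04). Protocadherins, adhesion molecules that give neurons their identity, fell in 17 of 48 cases and in 28 adjusted over the list alone (median -0.30, or -0.19 with quantile normalization, camera adjusted p = 5.47e-11, adjusted p = 0.0508 with an estimated correlation). Pcdhb8 fell by 0.78, Pcdhb17 by 0.60, Pcdhga6 by 0.59 and Pcdhgb6 by 0.48.

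Among the zinc finger genes, a class that HUSH and its partners silence, 9 of 342 rose and 22 fell, and 9 and 20 adjusted over the list alone (camera adjusted p = 0.738). The largest change named was that of Zfp970, which fell from 7.35 ± 0.711 to 2.65 ± 0.432 FPKM (-1.32, SE 0.11, adjusted p = 7.50e-04). Of 13 tested genes of the cluster around Zfp970 on chromosome 2, 7 were lower. Zfp783 fell by 0.98, Zfp760 by 0.61 and Zfp692 by 0.51. Of 13 tested HUSH genes and partners, Morc2a was the only one called (camera adjusted p = 0.257). Histone genes of the replication-dependent clusters rose in 9 of 18 cases, with 10 higher and 1 lower adjusted over the list alone (median 0.42, camera adjusted p = 2.57e-06, adjusted p = 0.0508 with an estimated correlation). Hist1h1c and Hist1h2bc, at 0.41 and 0.43, lost their calls without S87L replicate 1 or S87L replicate 2 (adjusted p up to 0.0685 and 0.0599). In the same libraries muscle and meninges lists were higher (medians 1.67 and 0.34), and intronic small RNA features lay below their host genes (median difference -0.42). No proliferation gene of 18 was called, with 1 at an unadjusted limma p under 0.05 (camera adjusted p = 0.976).

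Cdkn1a, the p53 target that stops the cell cycle (chromosome 17, 29090976 to 29100727), rose from 17.2 ± 0.943 to 33.7 ± 1.06 FPKM (log2 fold change 0.95, SE 0.05, adjusted p = 8.71e-05). Ccng1, Sesn1 and Gadd45a, of the same response, rose by 0.52, 0.35 and 0.31. Of 39 p53 and DNA damage genes, 8 rose and 3 fell, and 11 and 3 adjusted over the list alone (median 0.04, or 0.07 with quantile normalization and 0.02 with the GC and length trend removed, camera adjusted p = 0.00651, adjusted p = 0.0837 with an estimated correlation). Of 28 genes of the integrated stress response and UPR, 17 rose, and 20 rose and 1 fell adjusted over the list alone (median 0.21, camera adjusted p = 9.21e-10, adjusted p = 0.0524 with an estimated correlation). They included the endoplasmic reticulum chaperone Hspa5, from 113 ± 2.15 to 140 ± 1.88 FPKM, its cofactor Sdf2l1 (0.69), Nupr1 (0.66) and the folate enzyme Mthfd2 (0.43). Heat shock genes rose in 9 of 14 cases and in 10 adjusted over the list alone (median 0.25, camera adjusted p = 2.24e-08, adjusted p = 0.0508 with an estimated correlation). Hspa1b rose by 1.36, Hspa1a by 0.71, Dnajb1 by 0.43 and Hsph1 by 0.42. In the same libraries the muscle and meninges lists were higher (medians 1.67 and 0.34).

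The NRF2 antioxidant list, which answers to oxidants, showed little movement, with 2 of 38 higher and 1 lower, and the same adjusted over the list alone (camera adjusted p = 0.355). Its median of -0.00 and mean of 0.01 differed in sign, and the sign of the median depended on the scaling. The glutathione transferase Gstm1 rose from 144 ± 3.17 to 165 ± 1.44 FPKM (0.19, SE 0.03). Of 79 nuclear-encoded respiratory chain genes, Uqcrfs1 was called higher, by 0.14, a call lost without any 1 of the 6 libraries (adjusted p = 0.0573 to 0.173) and lost adjusted over the list alone (camera adjusted p = 0.357). Limma called 0 of 11 mitochondrially encoded genes, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.680). Cholesterol synthesis genes fell in 12 of 21 cases and in 15 adjusted over the list alone (median -0.18, camera adjusted p = 3.17e-05, adjusted p = 0.0732 with an estimated correlation), among them Lss (-0.35), Fdft1 (-0.28) and Cyp51 (-0.22). This went with higher muscle and meninges lists (medians 1.67 and 0.34) and intronic small RNA features below their host genes (median difference -0.42). Limma called 0 of 78 ribosomal protein genes, with 11 at an unadjusted p under 0.05. As a list they were called higher (median 0.04, camera adjusted p = 0.00236, adjusted p = 0.653 with an estimated correlation), a call lost without wild-type replicate 2 (adjusted p = 0.135), with fry (0.405), with quantile normalization (0.270, median 0.02) and with the GC and length trend removed (0.174, median 0.00).

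Microglia and macrophage genes rose in 16 of 27 cases, and 17 rose and 1 fell adjusted over the list alone (median 0.28, camera adjusted p = 5.61e-11, adjusted p = 0.0524 with an estimated correlation). The signalling adaptor Tyrobp rose from 19.5 ± 0.342 to 27.9 ± 1.46 FPKM (log2 fold change 0.51, SE 0.05, adjusted p = 0.00105). Laptm5 rose by 0.45, the complement gene C1qc by 0.44 and the protease Ctss by 0.34. Muscle, meninges and red blood cell lists were higher in the same libraries (medians 1.67, 0.34 and 0.23). Interferon-stimulated genes rose in 6 of 27 cases, and 7 rose and 1 fell adjusted over the list alone (median 0.14, or 0.25 with quantile normalization, camera adjusted p = 5.47e-04, adjusted p = 0.0743 with an estimated correlation), with Isg15 at 0.64 and Bst2 at 0.42. Among 11 cytokine and chemokine genes 2 rose and 2 fell, and 3 and 4 adjusted over the list alone (camera adjusted p = 0.331). The NF-kB inhibitor Nfkbia rose by 0.66 and Il18 fell by 0.37. Of 8 neutrophil and lymphocyte genes limma called 0, with 3 at an unadjusted p under 0.05, and 2 fell adjusted over the list alone (camera adjusted p = 0.878). The mean of that list was -0.05 and its median 0.03, with a sign that depended on the scaling.

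Reactive astrocyte genes rose in 7 of 23 cases and fell in 3, and 10 and 3 adjusted over the list alone (median 0.13, or 0.23 with quantile normalization, camera adjusted p = 0.00118, adjusted p = 0.193 with an estimated correlation). Serping1, a complement inhibitor, rose by 0.76, and Serpina3n and C4b each by 0.29. Of 14 general astrocyte genes 4 rose and 1 fell, also adjusted over the list alone (median 0.07, camera adjusted p = 0.0147, adjusted p = 0.119 with an estimated correlation), a call lost without wild-type replicate 1 (adjusted p = 0.0614) and with quantile normalization (0.160). The median was 0.04 with the GC and length trend removed. Muscle, meninges and red blood cell lists rose beside them (medians 1.67, 0.34 and 0.23). The gap junction gene Gjb6 rose from 48.4 ± 1.63 to 65.4 ± 0.589 FPKM (0.43, SE 0.04). Of 26 oligodendrocyte genes 3 rose and 5 fell, and 5 and 7 adjusted over the list alone (camera adjusted p = 0.803), with the myelin gene Opalin at -0.87. Of 10 ependymal genes 1 rose and 3 fell, and 1 and 4 adjusted over the list alone (camera adjusted p = 0.331).

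Of 27 motor neuron genes 2 rose, also adjusted over the list alone (camera adjusted p = 0.193). The retinoic acid enzyme Aldh1a2, which the meninges also make, rose by 0.73. Of 29 neuronal and synaptic genes 4 fell, and 6 adjusted over the list alone (camera adjusted p = 0.344, and 0.0102 lower with quantile normalization). The glutamate transporter Slc17a7 fell from 2.06 ± 0.261 to 0.401 ± 0.0727 FPKM (0.353-fold, SE 0.11 on the log2 scale, adjusted p = 4.62e-04). Of 25 neuronal injury genes 1 rose and 5 fell, and 2 and 5 adjusted over the list alone (camera adjusted p = 0.138, and 0.0484 lower with quantile normalization), with the neuropeptides Vip and Npy at -0.56 and -0.34. Of 22 immediate early genes 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.228), with Zfp36 at 0.65.

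As lists, markers of meninges and fibroblasts, Schwann cells, endothelium and pericytes, and red blood cells were higher in S87L libraries. Meninges and fibroblast genes rose in 9 of 17 cases and in 11 adjusted over the list alone (median 0.34, camera adjusted p = 6.03e-10, adjusted p = 0.0920 with an estimated correlation). The matrix proteoglycan Dcn rose from 4.67 ± 0.216 to 11.6 ± 0.451 FPKM (1.22, SE 0.05, adjusted p = 4.56e-05), Ogn by 1.14 and Col1a1 by 1.09. The fibroblast matrix and contractile list, which shares genes with it, rose in 16 and fell in 3 of 33 cases, and in 18 and 4 adjusted over the list alone (median 0.21, camera adjusted p = 3.18e-07, adjusted p = 0.0837 with an estimated correlation), with the growth factor Ccn2 at 0.70. Schwann cell genes rose in 4 and fell in 1 of 12 cases, and in 6 and 1 adjusted over the list alone (median 0.12, camera adjusted p = 0.00522, adjusted p = 0.0920 with an estimated correlation), and Prx, which encodes periaxin, rose by 0.51. Endothelial and pericyte genes rose in 7 and fell in 2 of 20 cases, and in 9 and 2 adjusted over the list alone (median 0.09, camera adjusted p = 0.00250, adjusted p = 0.166 with an estimated correlation). The smooth muscle genes Acta2 and Tagln of that list rose by 1.02 and 0.86, and the endothelial receptor Kdr fell by 0.66. Red blood cell genes rose in 3 of 8 cases and in 4 adjusted over the list alone (median 0.23, camera adjusted p = 0.0140, adjusted p = 0.266 with an estimated correlation), with Hbb-bs at 0.30.

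**Figure D3:**
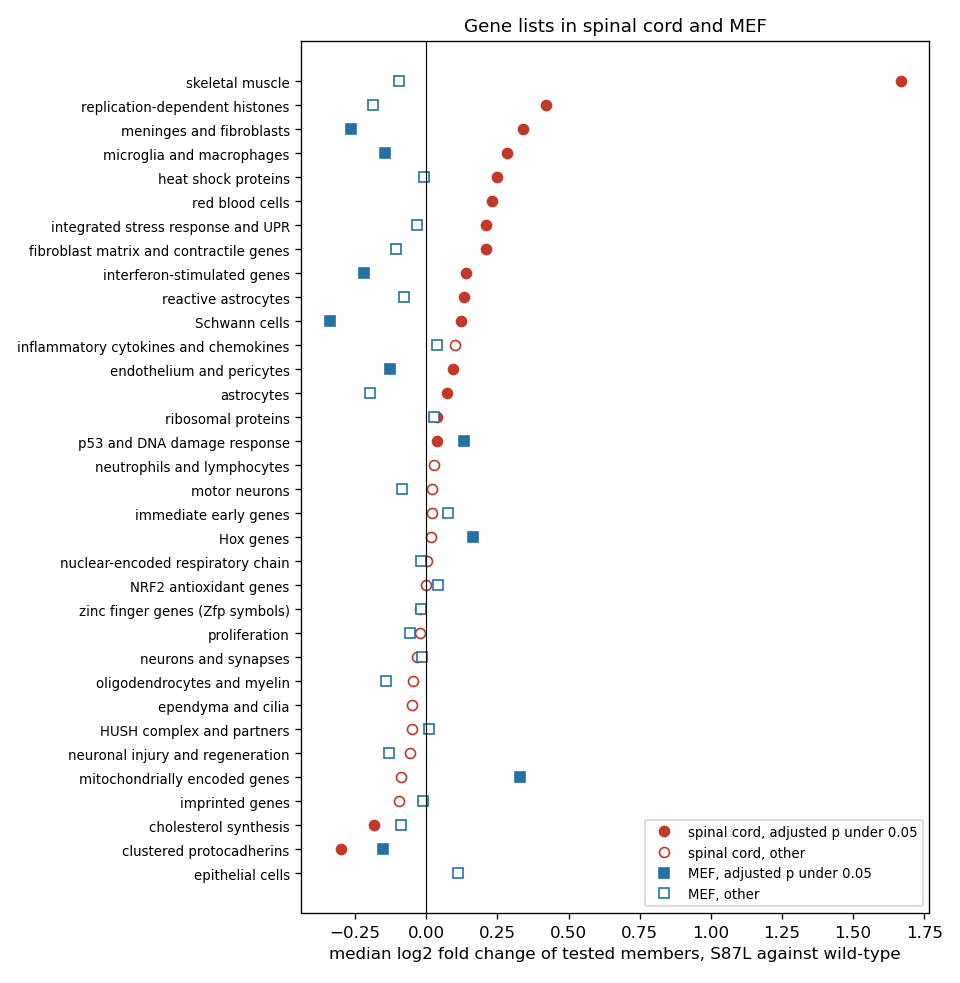
Median log2 fold change (S87L minus wild-type) of the members of each tested gene list. Circles are spinal cord and squares are MEF, and filled symbols have a camera adjusted p under 0.05 at the preset correlation.

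The MEF comparison asks what the genotype changes in a cultured cell type outside the nervous system. Eln, Mfap4 and Lum, which encode extracellular matrix proteins, fell, and the p53 targets Ccng1 and Pmaip1 rose. Of 13773 genes tested, limma called 1547, 676 higher and 871 lower in S87L. The median size of a called change was 0.37 on the log2 scale. Changes of at least 1.5-fold numbered 84 higher and 252 lower, and of at least 2-fold 20 and 73. The groups did not overlap at any of the 1547 called genes, or at 6302 of all genes tested, where chance gives 20% for 3 against 2. The count was 616 without wild-type replicate 1, 587 without wild-type replicate 2, 565 without wild-type replicate 3 and 858 without S87L replicate 1. It was 788 with no filter on low values, 2729 with voom on recovered reads and 182 with the replicate number as a block.

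Eln, the elastic fibre protein, fell from 239 ± 0.806 (SD, n = 3) to 80.4 ± 12.6 FPKM (SD, n = 2; log2 fold change -1.57, SE 0.09, adjusted p = 9.86e-04). The microfibril protein Mfap4 fell from 113 ± 2.16 to 38.3 ± 0.253 FPKM (-1.55, SE 0.04, adjusted p = 5.28e-05), and the Wnt modulator Sfrp2 by 1.56. The cartilage collagen Col9a2 and Olfml1 changed by -1.76 and -1.53. The collagenase Mmp13 rose from 3.15 ± 0.0507 to 8.01 ± 0.867 FPKM (1.22, SE 0.08), Klra4 by 1.85, the mast cell protease Mcpt8 by 1.30 and the zinc finger gene Zfp992 by 1.22. Klra4 lay near the filter on low values and passed it in 4 of the 5 fits with 1 library left out. The other largest changes were small RNA features on few reads, and no fold is given for them. Snord59a, Snord32a, Mir7660, Mir7017 and Mir7674 were listed at 0 in all wild-type libraries and had 4, 4, 3, 2 and 2 reads over both S87L libraries, and Snord58b had 3 and 6 reads. Mir544, Mir431, Mir142 and Mirlet7a-2 were listed at 0 in both S87L libraries, against 7, 6, 4 and 4 reads, and mt-Ta had 15 reads against 2. Of the 5 fits with 1 library left out, Mir7017 and Mir7674 passed the filter on low values in only 3. Snord59a, Snord32a, Mir7660 and Mirlet7a-2 passed it in 4. Calls of these features could not be checked in the remaining fits. The calls of Mir431 (adjusted p up to 0.106, without wild-type replicate 2, S87L replicate 1 or S87L replicate 2), Mir142 (0.0578, S87L replicate 1) and Mirlet7a-2 (up to 0.0709, S87L replicate 1 or 2) were lost with 1 library left out.

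Genes of the p53 and DNA damage response rose in 11 of 41 cases, and 15 rose and 2 fell adjusted over the list alone (median 0.13, camera adjusted p = 3.76e-04, adjusted p = 0.285 with an estimated correlation). Ccng1 rose from 97.1 ± 0.939 to 150 ± 10.4 FPKM (log2 fold change 0.62, SE 0.05, adjusted p = 0.00149). The cell death gene Pmaip1 rose by 0.78, the p53 ligase Mdm2 by 0.49 and the kinase Plk2 by 0.37. Hox genes rose in 10 and fell in 2 of 33 cases, and in 12 and 2 adjusted over the list alone (median 0.16, camera adjusted p = 0.00339, adjusted p = 0.285 with an estimated correlation). Hoxb9 rose by 0.60 and Hoxa5 by 0.57, and Hoxc12 and Hoxd13 fell by 1.24 and 0.38. Mitochondrially encoded genes rose in 5 and fell in 1 of 10 cases, and in 7 and 1 adjusted over the list alone (median 0.33, camera adjusted p = 0.00562, adjusted p = 0.457 with an estimated correlation). The list's call was lost with quantile normalization (adjusted p = 0.0579) and with fry (0.0542), and its median was 0.18 with the GC and length trend removed. The respiratory subunits mt-Nd1 and mt-Nd5 were called higher, at 0.34 and 0.56, and both calls were lost without any 1 wild-type library (adjusted p up to 0.0743 and 0.0727).

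Meninges and fibroblast genes fell in 5 and rose in 1 of 14 cases, and in 7 and 1 adjusted over the list alone (median -0.26, camera adjusted p = 0.00271, adjusted p = 0.285 with an estimated correlation). Lum, a collagen-binding proteoglycan, fell from 50.1 ± 0.803 to 21.5 ± 0.275 FPKM (-1.20, SE 0.04), Ccn3 by 0.96, Dcn by 0.92 and Islr by 0.89. In the fibroblast matrix and contractile list 13 of 40 fell and 5 rose, and 18 and 11 adjusted over the list alone (camera adjusted p = 0.167, and 0.0461 lower with quantile normalization). Endothelial and pericyte genes fell in 4 and rose in 1 of 13 cases, and in 5 and 1 adjusted over the list alone (median -0.13, camera adjusted p = 0.0334, adjusted p = 0.457 with an estimated correlation). That call was lost without wild-type replicate 1 (adjusted p = 0.0501), without S87L replicate 1 (0.109), with the replicate number as a block (0.0795) and with the GC and length trend removed (0.0521). The smooth muscle myosin Myh11 fell by 0.71. Schwann cell genes fell in 4 of 8 cases, also adjusted over the list alone (median -0.34, camera adjusted p = 0.00820, adjusted p = 0.457 with an estimated correlation), with the neurotrophin receptor Ngfr at -0.66 and Pmp22 at -0.37. Microglia and macrophage genes fell in 7 and rose in 2 of 23 cases, and in 13 and 2 adjusted over the list alone (median -0.14, camera adjusted p = 0.00889, adjusted p = 0.285 with an estimated correlation). Its members Spp1, a secreted matrix protein also made by fibroblasts, and Tmem119 moved from 168 to 338 FPKM and by -0.42 on the log2 scale.

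Interferon-stimulated genes fell in 7 of 20 cases, and 8 fell and 1 rose adjusted over the list alone (median -0.22, camera adjusted p = 5.08e-04, adjusted p = 0.285 with an estimated correlation), with Ifi27 at -0.69 and the tetherin gene Bst2 at -0.41. Protocadherins fell in 2 and rose in 1 of 30 cases, also adjusted over the list alone (median -0.15, or -0.09 with quantile normalization, camera adjusted p = 0.0118, adjusted p = 0.572 with an estimated correlation), a call lost without S87L replicate 2 (adjusted p = 0.375), with quantile normalization (0.0634) and with fry (0.0943). The calls of the 3 genes, Pcdhga2, Pcdhb17 and Pcdhgb2, were lost without any 1 of the 5 libraries (adjusted p up to 0.105, 0.0931 and 0.141). Of 319 zinc finger genes 10 rose and 15 fell, and 6 and 12 adjusted over the list alone (camera adjusted p = 0.828). Zfp992 rose by 1.22 and Zfp991 by 1.01, and Zfp970 fell by 1.19. Of 12 HUSH genes and partners Morc2a was the only one called (camera adjusted p = 0.794). Imprinted genes rose in 3 and fell in 6 of 27 cases, and in 4 and 8 adjusted over the list alone (camera adjusted p = 0.975). Peg10 (chromosome 6, 4747306 to 4760517) rose from 12.3 ± 0.154 to 24.8 ± 1.503 FPKM (0.98, SE 0.05, adjusted p = 4.92e-04), and Dlk1, Ndn and the growth inhibitor Cdkn1c fell by 0.74, 0.61 and 0.50.

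Other MEF lists were not called. Of 39 NRF2 antioxidant genes 3 rose and 4 fell, and 5 and 6 adjusted over the list alone (camera adjusted p = 0.236, and 0.0346 without S87L replicate 1), with Gstm2 at -0.53. Limma called 0 of 79 nuclear-encoded respiratory chain genes, with 3 at an unadjusted p under 0.05 (camera adjusted p = 0.999), and 0 of 78 ribosomal protein genes, with 2 (camera adjusted p = 0.103, and 0.00359 higher with the GC and length trend removed). Both lists took opposite directions when S87L replicate 1 or S87L replicate 2 was left out. The respiratory list was higher at an adjusted p of 0.00104 and lower at 0.00433, and the ribosomal list higher at 8.08e-10 and lower at 0.0282. Of 23 cholesterol synthesis genes 6 fell, and 8 adjusted over the list alone (camera adjusted p = 0.0518, 0.0307 without S87L replicate 1, 0.0414 with quantile normalization and 0.0239 with the GC and length trend removed). Of 24 immediate early genes 8 rose and 2 fell, and 9 and 2 adjusted over the list alone (camera adjusted p = 0.0518, 0.0269 without S87L replicate 1 and 0.00140 with the GC and length trend removed), with Fosl1 at 0.69 and Junb at 0.40. Of 9 oligodendrocyte genes 2 fell, also adjusted over the list alone (camera adjusted p = 0.0518, and 0.0449 without wild-type replicate 3).

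Of 19 cytokine and chemokine genes in MEF 2 rose and 3 fell, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.430). The prostaglandin enzyme Ptgs2 rose by 1.01 and the adhesion molecule Icam1 fell by 0.79. Of 31 integrated stress response and UPR genes 2 fell, also adjusted over the list alone (camera adjusted p = 0.485), with Slc7a5 at -0.34. Of 14 heat shock genes 2 rose and 1 fell, and 3 and 1 adjusted over the list alone (camera adjusted p = 0.794, direction higher, against a median of -0.01), with Cryab at -0.38. Of 35 histone genes 2 fell (camera adjusted p = 0.179), and of 30 proliferation genes 1 rose and 1 fell (camera adjusted p = 0.179), or 1 fell adjusted over the list alone. Of 20 reactive astrocyte genes 3 rose and 5 fell (4 and 7 adjusted over the list alone), of 8 astrocyte genes 1 and 2 (2 and 3), of 10 motor neuron genes 2 fell (2 rose and 4 fell), of 11 neuronal genes 2 rose (2 and 2), of 16 neuronal injury genes 2 rose (2), of 5 muscle genes 1 and 2 (1 and 2) and of 5 epithelial genes 1 rose (1 and 1). Their camera adjusted p lay between 0.309 and 0.794 apart from that of neurons and synapses at 0.954. The epithelial list had a median of 0.11 and a mean of -0.04. Red blood cells, neutrophils and lymphocytes and ependyma in MEF, epithelial cells in spinal cord, and sex-linked genes in both had under 5 tested members and were not tested as lists.

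Whether the genotype effect differed between tissues was tested over 12389 genes. The proteoglycan Dcn (chromosome 10, 97479609 to 97518143) rose in spinal cord and fell in MEF, a difference (MEF effect minus spinal cord effect) of -2.14 (SE 0.08, limma adjusted p = 8.79e-08). Lum, Prelp, Apod and the corepressor Hr did the same, with differences of -1.79, -1.71, -1.51 and -1.82. Hoxa10, Hoxc10 and Meg3 differed the other way, by 2.08, 1.71 and 1.18, with falls in spinal cord and no call in MEF. Cd24a fell in spinal cord (-0.25) and rose in MEF (0.80), and Spp1 was called in MEF alone among these fits (difference 0.92). Limma called 1632 genes, 747 with a higher and 885 with a lower effect in MEF, and at 1267 of them the effects had opposite signs. The 1267 take the sign of every effect, called or not, and a test of the difference favours genes with opposite signs. Called in both tissues with opposite signs were 74 genes higher in spinal cord and 24 higher in MEF. The number of called differences was 960 with the replicate number as a block, and all 10 named genes kept their calls in every setting run.

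Of 30 lists, 14 differed between tissues at the preset correlation, 3 with a higher and 11 with a lower effect in MEF. Hox genes (camera adjusted p = 3.50e-07), protocadherins (0.00241) and mitochondrially encoded genes (0.0149) had the higher effect in MEF, with adjusted p = 0.0574, 0.175 and 0.353 with an estimated correlation. The mitochondrial difference was lost without S87L spinal cord replicate 2 or S87L MEF replicate 1 (adjusted p up to 0.0570). The lists of meninges and fibroblasts (5.09e-11), fibroblast matrix and contractile genes (9.38e-08), microglia (9.38e-08), muscle (2.71e-07), the integrated stress response and UPR (3.50e-07), interferon-stimulated genes (1.55e-06), heat shock (7.91e-04), Schwann cells (0.00123) and histones (0.00296) had a lower effect in MEF. These 9 were also called with an estimated correlation. Endothelium and pericytes (0.00108) and reactive astrocytes (0.00988) were lower too, at adjusted p = 0.0701 and 0.175 with an estimated correlation, and the latter was lost without wild-type MEF replicate 2 (0.0525).

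Calls were shared between the tissues more often than independent lists give in 3 of the 4 combinations of direction, 1 of them with opposite signs. Fisher's exact test treats genes as independent, which they are not, so its p-values may be too small. Higher in both were 58 genes against 31.7 for independent lists (Fisher's exact test, odds ratio 2.01, adjusted p = 1.10e-05), and lower in both 103 against 50.3 (2.39, adjusted p = 6.00e-12). Higher in spinal cord and lower in MEF were 74 against 40.2 (2.05, adjusted p = 4.78e-07). Lower in spinal cord and higher in MEF were 24, fewer than the 39.7 of independent lists (0.576, adjusted p = 0.00684). Of 259 genes called in both tissues, 161 had the same sign. Across all 12389 genes, which are not independent replicates, the fold changes correlated weakly (Pearson 0.1004, Spearman 0.0983), and 53.9% had the same sign. Peg10 (0.52 in spinal cord, 0.98 in MEF), the EGF receptor inhibitor Errfi1 (0.55 and 0.64) and Ccng1 (0.52 and 0.62) rose in both. Zfp970 (-1.32 and -1.19) and Rps4l, a paralog of ribosomal protein S4, (-0.81 and -1.06) fell in both, and Mir544 was lower in both on few reads. Dcn, Hr, Prelp and the myosin light chain Myl9 (0.58 and -0.62) rose in spinal cord and fell in MEF.

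**Figure D4:**
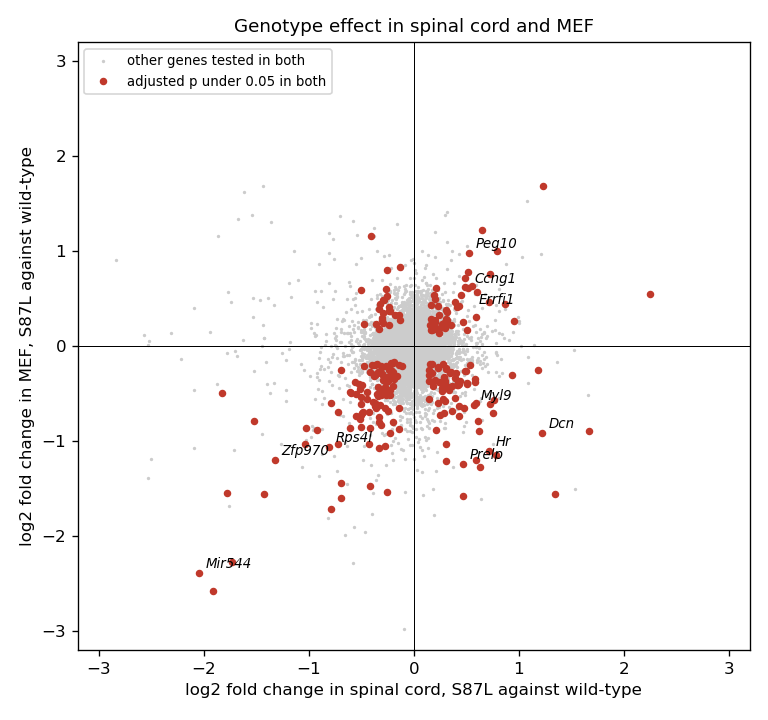
Log2 fold change (S87L minus wild-type) in MEF against that in spinal cord for the 12389 genes tested in both. Red points are the 259 genes called in both tissues, grey points are the others, and 10 named genes are labelled.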

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

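These results were brought up by the test of the difference of the genotype effect between tissues, which found a difference for 1632 genes. The differences, MEF effect minus spinal cord effect, were 0.92 for Spp1, 2.08 for Hoxa10, 1.05 for Cd24a, 1.18 for Meg3 and 1.71 for Hoxc10. They were -1.71 for Prelp, -2.14 for Dcn, -1.51 for Apod, -1.82 for Hr and -1.79 for Lum. Lists with a higher effect in MEF were clustered protocadherins (camera adjusted p = 0.00241), Hox genes (3.50e-07) and mitochondrially encoded genes (0.0149). Lists with a lower effect in MEF were microglia and macrophages (9.38e-08), interferon-stimulated genes (1.55e-06), reactive astrocytes (0.00988), Schwann cells (0.00123), endothelium and pericytes (0.00108) and meninges and fibroblasts (5.09e-11). The others were skeletal muscle (2.71e-07), fibroblast matrix and contractile genes (9.38e-08), replication-dependent histones (0.00296), the integrated stress response and UPR (3.50e-07) and heat shock proteins (7.91e-04).

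Lower caudal Hox genes and higher muscle genes in S87L spinal cord were examined with 3 tests, all chosen after the result was seen. A smaller share of caudal cord in the S87L pieces may lower caudal Hox genes. The Spearman correlation of fold change with paralog number was -0.333 over 26 genes in cord (permutation p = 0.0977). In MEF it was -0.625 over 33 genes (permutation p = 1.20e-04). A correlation over all Hox genes asks for a steady slope, which a loss of caudal genes alone need not give, so it cannot decide this explanation. In cord the median was 0.05 for groups 1 to 8 and -1.31 for groups 9 and up, and in MEF it was 0.38 and -0.05. The MEF correlation thus rests largely on higher genes in low groups, and the cord medians differ mainly through lower genes in groups 9 and up. Of the Hox genes called in both tissues, Hoxa5 (0.60 in cord, 0.57 in MEF) and Hoxc5 (0.86 and 0.44) rose in both. Hoxb9 fell in cord (-0.51) and rose in MEF (0.60). Muscle carried over with the S87L cords may raise muscle transcripts, and 14 of 15 muscle genes rose, which also fits any other source of muscle RNA. The muscle list shares no gene with the other lists, while the meninges list shares Col1a1, Col1a2, Col3a1, Dcn and Lum with the matrix list. Levels in S87L cord were 20.6 FPKM for Acta1 and 12.6 for Tnnt3, with no muscle library to compare them with. A genotype effect on caudal Hox genes in both tissues could be the source, but 6 of the 7 Hox genes lower in cord were tested in MEF with a median log2 fold change of -0.0199, which speaks against it for these genes. Hoxc12 (-1.24) and Hoxd13 (-0.38), not tested in cord, fell in MEF, calls that held with any 1 library left out but not with a replicate block (adjusted p = 0.0790 and 0.0770).

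The small spread between libraries of a group was examined with a test of spread, chosen after the result was seen, and with splits of the libraries, chosen before. If the libraries of a group came from 1 animal or pool, genes that vary with dissection may not vary more than others, but in spinal cord their spread beyond counting was 1.63 times that of other genes, which does not decide it. In MEF the value for immediate early genes lies at the floor of 0%, against 1.91% for other genes, and decides nothing, so this explanation stays open. Of the 10 splits of the 6 spinal cord libraries, 1 reached the count of the real split, the real split itself (2016 genes, highest other 0), and for lists also 1 (17 lists, highest other 12), but 10 splits are too few for a share under 0.05. Every other split mixed the genotypes and called 0 genes, yet camera at the preset correlation called 3 to 12 lists in each. Each of these splits still held more libraries of 1 genotype on 1 side, so part of the genotype difference remained in it. The list calls there may come from that part or from another structure, and these splits cannot tell which. Mixing the genotypes also widens the spread within each side, so the 0 called genes are no measure of false calls. The split of wild-type replicate 1 with S87L replicates 1 and 2 against the rest gave 1696 genes at an unadjusted p under 0.05, which points to a structure of the samples. Wild-type replicate 1 stood apart from replicates 2 and 3 (spread beyond counting 6.01% and 4.99%, against 1.96% between those). S87L replicate 3 stood apart from replicates 1 and 2 (5.26% and 3.74%, against 1.86%).

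Zinc finger genes of 2 clusters were called in both tissues, with 5 lower on chromosome 2 (Zfp970, Gm14403, Gm14295, Gm14305, Gm14399) and 4 higher on chromosome 4 (Zfp991, Znf41-ps, Zfp992, Gm13245), and the tests of summed reads and of silencing, with their bounds, were chosen after these values were seen. With 1 library left out, calls of Gm14305, Zfp992, Gm14399 and Gm13245 were lost in at least 1 tissue (adjusted p up to 0.0997, 0.0736, 0.129 and 0.142), and those of the other 5 genes held in both. Stronger silencing of zinc finger genes could lower the chromosome 2 cluster, but 4 genes of the chromosome 4 cluster were higher in both tissues, and Zfp991 and Znf41-ps among them held with any 1 library left out, which speaks against it as the sole cause for both clusters. Reads divided differently among paralogs may mimic such changes, but the reads summed over the chromosome 2 cluster fell too (log2 ratio -0.514 in cord, -0.79 in MEF). The chromosome 4 sum rose in cord (0.224, from 75.0 ± 2.87 to 87.6 ± 2.49 parts per M) and in MEF (0.29, from 139 ± 3.79 to 169 ± 1.61). These sums speak against a division of reads among the summed genes alone as the whole cause. Reads that match several copies, or copies outside the summed genes, may be missing from the sums. How such reads were counted is not given, so a cause of that kind stays open. A C57BL/6J against C57BL/6N background could also differ at such clusters, but Nnt, which carries a known deletion in C57BL/6J, reached at most 0.149 FPKM in any library, which cannot tell the substrains apart here.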

How the results depend on the processing

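No named gene turned its direction with a call in any setting run. Of 124 named calls in spinal cord 37 were lost in at least 1 setting, and 77 of 111 in MEF, while the 10 named differences between tissues kept their calls. Of 64 list results 25 lost and 18 gained a call in at least 1 setting. The count of called genes moved with the setting, and the causes were not tested. In spinal cord, library weights gave 3098 calls (1331 higher) and removal of the GC and length trend 3315 (1219 higher, 2096 lower). Leaving out 1 library gave 838 to 1637 calls (344 to 758 higher, 494 to 879 lower). In MEF, no filter gave 788 (327 higher, 461 lower), 1 fit of all 11 libraries 1040 higher, limma without trend and robust settings 380 higher, and voom 2729 (1359 higher, 1370 lower). Leaving out 1 MEF library gave 565 to 1753 calls (202 to 829 higher, 363 to 924 lower), and without an S87L library the other is assumed to vary like the wild-type group. With an estimated correlation 1 list was called in spinal cord and 0 in MEF, and fry called 23 and 15. In spinal cord the lists called by fry and not by camera were all lower. They were imprinted genes (fry adjusted p = 5.04e-04), neurons and synapses (0.0128) and neuronal injury (0.0131). The others were Hox genes (0.0178), oligodendrocytes (0.0276), HUSH genes (0.029) and zinc finger genes (0.043). In MEF such lists had a fry adjusted p of 0.0127 to 0.0475, all lower but immediate early genes. At an unadjusted p under 0.01, 91 genes were higher in both tissues and 45 lower in cord and higher in MEF. The MEF respiratory chain list turned higher without S87L replicate 1 (adjusted p = 0.00104; 0.00104 to 0.819 over libraries left out). The MEF ribosomal protein list turned lower without S87L replicate 2 (0.0282; 8.08e-10 to 0.204). Voom, the GC and length trend, and leaving out features under 200 bases were added after the data were seen.

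With the replicate number as a block (replicate block), 1663 genes were called in spinal cord, 182 in MEF (53 higher, 129 lower) and 960 in the difference between tissues. Whether the numbers pair the samples stays open. Deviations from the group means, correlated across genes, gave 0.149, -0.0505 and 0.111 for spinal cord libraries with the same number. For those with different numbers the values were -0.199 to 0.0873. In MEF the same-number values were -0.0696 and -0.0277. With 2 S87L MEF libraries the deviations mirror each other, so the MEF values cannot test pairing. Depth of 12.08 to 23.53 M reads limits changes of low genes and of short features with few reads.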

Other observations

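Some long noncoding RNAs fell in S87L spinal cord, and those named here were chosen after their values were seen. The nuclear RNAs Malat1 and Neat1 fell from 286 ± 7.93 to 170 ± 7.63 FPKM (SD, n = 3 each; log2 fold change -0.75, limma adjusted p = 9.97e-05) and from 8.87 ± 0.254 to 4.72 ± 0.0772 (-0.85). The neuronal RNAs Miat and Snhg11 fell by 1.07 and 1.11, and these 4 calls held with any 1 library left out. Rian (-0.25) lost its call without wild-type replicate 2 or 3 or S87L replicate 1 or 2 (adjusted p up to 0.0714). Of 382 lincRNAs tested in cord 12 rose and 51 fell, of 175 microRNA features 49 fell and of 93 snoRNA features 12 fell. In MEF, Malat1 (0.08, adjusted p = 0.211), Neat1 (0.01) and Meg3 (-0.07) were not called.

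Xist, the RNA of the inactive X chromosome, was present in all 11 libraries, at 17.3 to 28.3 FPKM in spinal cord and 35.01 to 44 in MEF. It fell in S87L cord from 26.1 ± 2.37 to 17.9 ± 0.852 FPKM (-0.53, limma adjusted p = 0.00447). The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at most 0.0206 FPKM in any library. Of the p53 genes, Ccng1 (0.52 in cord, 0.62 in MEF) and Trp53inp1 (0.45 and 0.54), the latter chosen after its values were seen, rose in both tissues. Both genes kept both calls with any 1 library left out. Cdkn1a (0.95 and 0.26) and Pmaip1 (0.52 and 0.78) also rose in both. With 1 library left out, Cdkn1a could lose its MEF call and Pmaip1 its cord call (adjusted p up to 0.0810 and 0.0645). Over the p53 list 8 rose and 3 fell in cord, and 11 rose and 0 fell in MEF.

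Less unspliced RNA in the S87L cord libraries may lower nuclear long noncoding RNAs and small RNAs read from introns, a hypothesis with 2 tests, the first chosen after the result was seen and the second before its own result. Of 139 intronic small RNA features, 111 were lower than their host gene, by a median of -0.424 (95% interval over resampled features -0.54 to -0.35), the direction this predicts, against 0.03 (-0.11 to 0.20) over 165 features in MEF. Their summed reads, in parts per M, were 173 ± 54.1 in wild-type and 100.3 ± 14.6 in S87L cord (SD over 3 libraries each), a wide spread between libraries. Small RNA features had already been seen lower, so this test largely restates them. In the second test, 26 of 34 long transcripts annotated within introns were lower in cord than the gene that holds them, by a median of -0.290 (95% interval over resampled transcripts -0.41 to -0.08), and 4 of the 34 were themselves called lower. In MEF the median was -0.11 (-0.22 to 0.09) over 33, and the difference between tissues was not tested. A change of nuclear RNA in the animal and a difference in RNA preparation predict the same. Intron reads of the raw data would measure unspliced RNA directly.

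Genes with a single coding exon, which the HUSH complex is known to bind when they lack introns, might be lower in S87L if silencing were stronger, a test fixed before its result was seen. The set tested left out the histone, protocadherin and Zfp lists, and camera did not call it lower (adjusted p = 0.676 in cord and 0.593 in MEF). Of 751 genes in cord 29 rose and 60 fell, against 716 and 866 of 12023 others, and of 612 in MEF 37 rose and 69 fell, against 590 and 724 of 10796 others. With the members of the 3 lists included, a test added after the result was seen, camera did not call the set either (adjusted p = 0.720 over 815 genes in cord and 0.477 over 682 in MEF). A lower level of some of these genes stays open.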
